A study of Mus musculus with 2 samples.

How the data were processed

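H3K4me2 ChIP-seq was done on liver of mouse embryos at 14.5 days in 2 biological replicates, each of pooled male and female embryos of strain B6NTac;B6NCrl/Lap per the labels, which also give DNA fragments of 300.0 to 500.0 bp. The 4 deposited peak lists, on mm10, are those of replicate 1, replicate 2, both replicates together, and the replicated peaks derived from these 3. Per the text deposited beside the lists, each list was made from filtered alignments and further files whose kind it does not give, 2 for replicate 1 and for both together and 1 for replicate 2. The aligner, the peak caller, its threshold and the rule for replicated peaks are not given in the sources used here. The signal value of each peak is the authors' measure of enrichment from the peak caller; what it is relative to is not stated, so it was not read as a fold. The p-value and q-value of each peak stand as -log10 in the deposited lists, whose lowest -log10 p lay between 2.00 and 2.05. Peaks with a -log10 q under 2 made up 8.63% of replicate 1 and 12.6% of replicate 2. Reads, depth and input control were not used here. Lists with different numbers of weak peaks can differ at the same locus without a difference in the mark.

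Positions are 1-based on mm10. Genes and TSSs came from GENCODE M21 basic annotation on GRCm38.p6, and 0 peaks ran past a chromosome end. The analysis used the 19 autosomes, X and Y, 21 chromosomes in all, and left out 12 peaks of replicate 1 and 9 of replicate 2 on other contigs. Computation was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A peak was shared when at least 1 bp overlapped a peak of the other list. Overlap, promoter occupancy and location classes were set against 1000 circular shifts of the peaks along their chromosome, with a one-sided permutation p. A promoter had a peak when any part lay within 1 kb of any TSS of the gene. Peaks were classed by their centre as promoter (within 1 kb of any TSS), then exon, intron or intergenic. Shares carry Clopper-Pearson intervals at 95%, for counting error only; with 2 replicates the SD is the only measure of spread between samples.

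Before the data were examined, 24 gene lists, 18 motifs, 10 loci, all main tests and the rule for named genes were fixed. The lists were erythroid, embryonic globins, hepatoblast and fetal hepatocyte, mature hepatocyte metabolism, hematopoietic stem and progenitor, megakaryocyte, myeloid and macrophage, lymphoid, endothelial, stellate and mesenchymal, cholangiocyte, neuron, heart and skeletal muscle, epidermis, lung and kidney, pancreas and intestine, developmental transcription factors, Hox, housekeeping, ribosomal protein, heme biosynthesis, cell cycle, H3K4 methylation machinery, and olfactory and vomeronasal receptors. Ahsp and Loricrin were not found under these symbols. Promoter occupancy of each list was compared with all other protein-coding genes by a 2-sided Fisher's exact test in each replicate, with Benjamini-Hochberg adjustment over the lists, and called at an adjusted p under 0.05 in both replicates in the same direction. Genes are the unit of that test, so its p describes these libraries and not new embryos. Covered length was the number of bases in peaks within 10 kb of the most 5′ TSS. The median of each list was ranked among 10000 random lists of the same size, matched on the CpG count within 500 bp of the TSS, and called when outside the central 95% in both replicates. Domains were replicated peaks merged over gaps of at most 1 kb.

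Motif matches on both strands were counted per kb in replicated peaks whose centre lay over 1 kb from a TSS, and in flanks 5 kb away outside any peak. The log2 ratio of peaks over flanks was compared with that of the reversed string, with a jackknife SE over chromosomes, and called where the 95% interval excluded 0. The strings were WGATAAR for GATA, CCMCRCCCW for KLF, TGCTGAGTCA for NFE2, GAGGAAGT for PU.1, TGTGGTTW for RUNX, CAAAGKYCA for HNF4A, GTTAATNWTTA for HNF1, TGTTTAC for FOXA, TTGCRYAAY for CEBP, CCGGAAGT for ETS, CCAATSR for NFY, CCASYAGRKGGC for CTCF, TGASTCA for AP1, CTAWWWWTAG for MEF2, TTCAGCACC for REST, GTTGCYWNGCAAC for RFX, CAGATGG for NEUROD and ATGCAAAT for OCT, in the IUPAC code.

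Named were, in each list, up to 4 members with the largest mean covered length and up to 3, alphabetically, with no promoter peak in either replicate. Also named were the protein-coding genes at the 10 widest domains and the 10 strongest replicated peaks, the gene nearest each of the 3 strongest unshared peaks of each replicate, and the genes of the loci. Well-known members of the erythroid list, and the other genes outside this rule, were chosen after their values were seen.

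The alternatives were peaks with a -log10 q of at least 2, the 29409 strongest peaks of each replicate, at least 50% of a peak covered, peaks merged before comparing, and promoter windows of 500 bp and 2.5 kb. Further ones were the most 5′ TSS alone, covered windows of 5 and 50 kb, unmatched or CpG-matched random lists, each replicate left out, other merging gaps, flanks at 20 kb, 500 bp around summits and each replicate's own list for motifs. Chosen after seeing the data were classes by any part of the peak, the comprehensive annotation, random lists matched on promoter signal or on the number of neighbouring genes, one gene per cluster, and permuted motifs with the same CpG content. The tests were checked on simulated data, in which 73 of 120 planted lists were called by promoter occupancy and 99 of 120 by covered length, and 4 and 9 of 300 lists without a planted difference. Both simulated replicates were made from the peaks of replicate 1, so these rates do not include the differences between the real replicates. In place of the fold enrichment planned for, the lists gave the signal value described above.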

Results

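H3K4me2, dimethylation of lysine 4 on histone H3, is a chromatin mark found at promoters and enhancers. It was mapped by ChIP-seq in the liver of mouse embryos at 14.5 days, an age at which this organ forms red blood cells and also holds hepatoblasts, the precursors of hepatocytes. The samples formed 1 group of 2 biological replicates, each made from pooled male and female embryos, so no contrast between conditions was possible. The deposited lists, in mm10 coordinates, held 43698 peaks for replicate 1 and 39221 peaks for replicate 2. Calling on both replicates together gave 42107 peaks, and the authors' list of replicated peaks held 37536. Peaks covered 2.08% of the genome in replicate 1 and 1.59% in replicate 2, a mean of 1.84% ± 0.344 (SD, n = 2). The median peak width was 792 bp in replicate 1 and 724 bp in replicate 2. The signal printed for a peak is the authors' own value. It was used to describe, rank or filter peaks within a list and to correlate shared peaks between the replicates. It also served to count weak peaks in each replicate and to match random gene lists on promoter signal. No read counts were used here, so the depth is unknown, and every confidence interval covers counting error only.

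The strongest H3K4me2 peaks recurred in both replicates. The 10 replicated peaks with the highest signal overlapped a peak in each replicate. The first was a peak of 7996 bp inside Runx1, a transcription factor gene needed for definitive blood formation, on chromosome 16 at 92692999 to 92700994. The next was 33.7 kb from Acot11 on chromosome 4, and the others lay at Vasp, Pten, Usp49 with the overlapping model Gm20517, Taok2, Tmem131l, Lrp8, Cdc42ep2, and Scamp4 with Adat3. Pten encodes a lipid phosphatase that restrains PI3 kinase signalling, Vasp an actin regulator and Lrp8 a lipoprotein receptor. Peaks found in a single replicate were weak by comparison. The strongest ones without an overlap in the other list were, in replicate 1, an intronic peak of Kdm6a on the X chromosome, a peak on chromosome 16 at 220 kb from Setd4, and a peak that overlapped Gata3 and its neighbours 4930412O13Rik and 9230102O04Rik. In replicate 2 they were a promoter peak of Kdm5d on the Y chromosome and intronic peaks of Slc2a9 and Zcchc4. Kdm6a and Kdm5d encode histone demethylases, and Gata3 a transcription factor of T cells.

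Of the 43686 replicate 1 peaks on the 21 chromosomes, 30067 were overlapped by at least 1 bp of a replicate 2 peak, which is 68.8% (95% Clopper-Pearson interval 68.4 to 69.3%). Circularly shifted lists gave a mean of 3.21% and at most 3.92%. In the other direction, 37926 of 39212 replicate 2 peaks, or 96.7% (96.5 to 96.9%), were overlapped by replicate 1, against 3.82% for shifted lists. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. Sharing followed the signal, by which the peaks of each replicate were split into 5 classes of equal size. In the lowest class of replicate 1 peaks 18.7% were shared, in the next 38.8%, and in the highest 100%, while the lowest class of replicate 2 reached 88.0%. The replicates had 41.3 Mb in common, 73.6% of the bases covered in either, and 97.7% of the bases of replicate 2 lay in peaks of replicate 1. Across the 30067 shared peaks the signal had a Spearman correlation of 0.905 and, on the log2 scale, a Pearson correlation of 0.908. Peaks are not independent replicates, so no p-value is attached to these correlations.

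**Figure D1:**
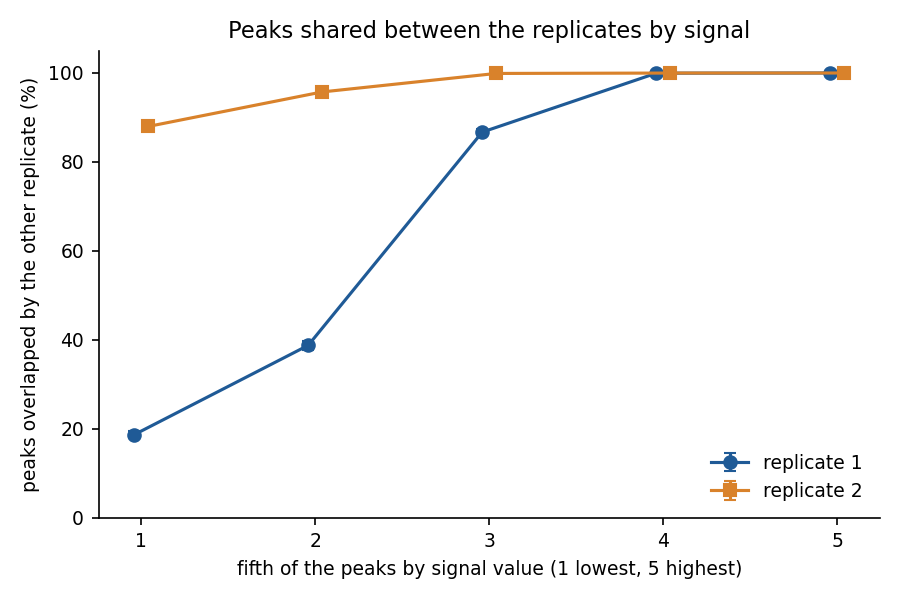
Percent of the peaks of each replicate overlapped by at least 1 bp of a peak of the other (y axis), in 5 classes of equal size from lowest to highest signal (x axis), with 95% Clopper-Pearson intervals. Replicate 1 (circles) went from 18.7% to 100% and replicate 2 (squares) from 88.0% to 100%.

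All 37536 replicated peaks had the coordinates of a peak called on both replicates together, so the authors kept 89.1% of those peaks and dropped 4571. Among the dropped peaks, 3282 were overlapped by replicate 1 alone and 304 by replicate 2 alone. Of 5 classes of equal size by signal, the lowest kept 55.2% of its peaks and the next 90.7%, whereas the highest kept 100%. Not every kept peak had a partner in each single list, since 29916 were overlapped by both at 1 bp and 7620 were not. For instance, a replicated peak inside Afp on chromosome 5 at 90492071 to 90492634 had a replicate 1 signal of 4.35 and no replicate 2 peak.

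Promoters of the erythroid programme carried the mark almost without exception. Of the 37 erythroid genes 35, or 94.6%, had a peak within 1 kb of a TSS in each replicate, including Gata1, Klf1, Tal1, Nfe2, Epor, Gypa, the band 3 gene Slc4a1, the spectrin genes Spta1 and Sptb and the adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt. The exceptions were Car1, a carbonic anhydrase gene, and Slc25a37, which encodes the mitochondrial iron importer mitoferrin-1. All 9 heme biosynthesis genes had a promoter peak in both replicates, among them Alas2, Alad, Hmbs, Cpox and Fech. Genes of mature hepatocyte metabolism mostly lacked one. Of 26 such genes 5 had a promoter peak in replicate 1 and 3 in replicate 2, namely Ass1, Aldob and Arg1 in both and Pck1 and Otc in replicate 1, a choice of names made after their values were seen. The urea cycle gene Cps1 and the cytochrome P450 genes Cyp1a2 and Cyp2c29 had none.

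Across all 21938 protein-coding genes, 14423 had a promoter peak in replicate 1 and 13823 in replicate 2, a mean of 64.4% ± 1.93 (SD, n = 2). Shifted peaks gave 5.92% and 4.78%, with a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. The same state was found in both replicates at 96.9% of genes. Occupancy followed the CpG content of the promoter. In the tenth of genes with the fewest CpGs 4.38% had a peak in replicate 1 and 3.56% in replicate 2, and in the tenth with the most 98.9% and 98.0%.

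Of the 24 gene lists fixed before the data were examined, 6 had promoter peaks more often than other genes and 8 less often, in both replicates, by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. The erythroid list had exact adjusted p = 0.000193 in replicate 1 and 5.6e-05 in replicate 2. Heme biosynthesis had 0.0491 and 0.0469, close to the threshold of 0.05. All 25 housekeeping genes, such as Polr2a and Eef2, all 22 cell cycle genes, such as Mki67, Pcna, Rrm2 and Aurkb, and all 15 genes of the H3K4 methylation machinery, such as Setd1a, Setd1b, Kmt2d and Kdm5a, had promoter peaks in both, with adjusted p of at most 0.00446. Of 83 ribosomal protein genes 80 had one (exact adjusted p = 2.15e-10 and 6.12e-12), and the 3 without were the paralogs Rpl10l, Rpl39l and Rpl3l.

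The lists with fewer promoter peaks than other genes were those of other organs, of immune cells and of mature hepatocyte metabolism (exact adjusted p = 9.16e-06 and 3.85e-07). Heart and skeletal muscle had peaks at 2 and then 1 of 20 genes in replicates 1 and 2 (2.89e-06 and 3.85e-07), with Ryr2 in both and none at Acta1, Actc1 or Casq1. Epidermis had 2 and 1 of 17 (3.13e-05 and 5.4e-06), with Krt10 in both and none at Col17a1, Dsg1a or Dsg3. Lung and kidney had 3 and 2 of 15 (0.000828 and 0.000239), and pancreas and intestine 2 of 16 in both (6.77e-05 and 0.000123), with Lgr5 and Cela1 occupied and none at Cdx1, Cdx2 or Cel. The myeloid list, which holds the macrophage genes Adgre1, C1qa and C1qb, had 6 and 0 of 25 (8.26e-05 and 1.25e-10), with a peak at Cd68 and Prtn3 in replicate 1. The lymphoid list had 9 and 6 of 22 (0.0355 and 0.00249), with Gata3, Ebf1 and Bcl11b occupied in both and no peak at Cd19, Cd2 or Cd3e. Of 1420 olfactory and vomeronasal receptor genes, 6 and 2 had a promoter peak, with a Fisher's exact p below the smallest number the software can write. Vmn1r4 was occupied in both.

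The other 10 lists were not set apart in both replicates. The hepatoblast list had promoter peaks at 32 of 38 genes in replicate 1 (adjusted p = 0.0274, Fisher's exact test) and at 22 in replicate 2 (0.552). Prox1, Foxa1, Hnf1a and Apom were occupied in both, while Ahsg, Apoa1 and Apoc3 had no promoter peak. At Apoa1 a peak found in both replicates began 1032 bp from the TSS, just outside the window. Stem and progenitor genes had 19 and 16 of 20 (0.00698 and 0.206), with Mpl, the thrombopoietin receptor gene, lacking a peak. Endothelial genes had 11 and 6 of 18 (0.919 and 0.0208), with Egfl7, Esam, Sox18 and Eng occupied in both. Hox genes had 21 and 16 of 39 (0.183 and 0.0121). The counts were 11 and 9 of 17 for megakaryocytes, 13 and 11 of 20 for stellate and mesenchymal cells, 7 and 6 of 10 for cholangiocytes, 12 and 10 of 22 for neurons, 25 and 20 of 34 for developmental transcription factors and 1 and 0 of 3 for embryonic globins.

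Ranked among random lists matched on promoter CpG content instead, the mature hepatocyte, myeloid, lymphoid, cell cycle and H3K4 machinery lists were no longer set apart in both replicates. The hepatoblast list then lay above random, at percentiles 100 and 98.0, and neurons, developmental transcription factors and Hox genes lay below, at percentiles of at most 0.83. The heme biosynthesis call also ended with windows of 500 bp or 2.5 kb and with equal numbers of peaks, and the lymphoid call with 2.5 kb.

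**Figure D2:**
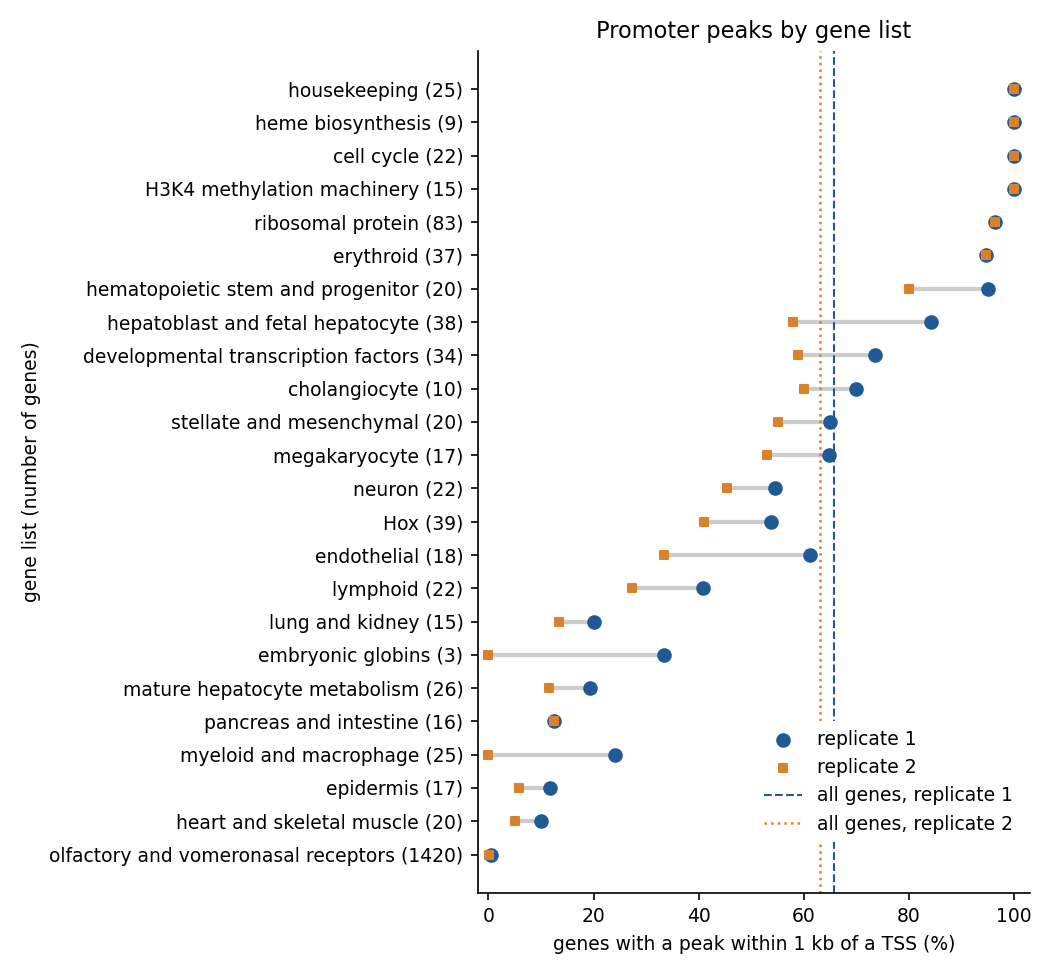
Percent of the genes of each list with a peak within 1 kb of a TSS (x axis) in replicate 1 (circles) and replicate 2 (squares), with the number of genes of each list in parentheses and the value over all protein-coding genes as vertical lines. Erythroid genes stood at 94.6% in both, hepatoblast genes at 84.2% and 57.9%.

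Erythroid genes, with the heme biosynthesis genes, also had the longest covered length of the 24 lists. The median erythroid gene had 9.57 kb covered by peaks within 10 kb of its TSS in replicate 1 and 8.34 kb in replicate 2, a mean of 8.95 ± 0.871 kb (SD, n = 2), against 1.39 and 0.982 kb for random lists of the same promoter CpG content. Slc4a1 on chromosome 11 had 15.9 ± 1.88 kb, the membrane skeleton gene Epb41 on chromosome 4 had 14.5 ± 0.344 kb, the transcription factor gene Tal1 had 13.8 ± 1.73 kb and Hba-a2 had 13.7 ± 1.01 kb (mean ± SD, n = 2). Among heme biosynthesis genes, Cpox had 13.2 ± 0.337 kb, Fech 12.8 ± 0.782 kb, Alad 12.2 ± 1.15 kb and Hmbs 10.3 ± 0.569 kb. Hba-a1 with Hba-a2 and Hbb-bs with Hbb-bt are near-identical copies, so their separate values are uncertain.

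The list medians were ranked among 10000 random lists matched on promoter CpG content, and 9 of the 24 lists lay above the central 95% of them in both replicates and 3 below, where chance would put 1.2 lists outside this range in a single replicate. All 12 calls held after Benjamini-Hochberg adjustment of the permutation p over the lists. Besides the erythroid list, heme biosynthesis had a mean of 8.95 ± 0.871 kb (SD, n = 2), both medians being the value of Alas2, which is in both lists. Stem and progenitor genes had 4.06 ± 0.720 kb, led by Lmo2 with 11.1 ± 1.40 kb, Meis1 with 9.51 ± 0.838 kb, Lyl1 with 9.02 ± 0.779 kb and Ikzf1 with 8.95 ± 1.57 kb. Hepatoblast genes had 2.65 ± 1.00 kb. Apom, the carrier of sphingosine 1-phosphate in plasma, had 8.57 ± 1.45 kb, and the liver transcription factor genes Prox1, Foxa1 and Hnf1a had 7.50 ± 1.46, 6.49 ± 1.90 and 5.57 ± 1.58 kb. Embryonic globins had 4.94 ± 0.573 kb over 3 genes, which is the value of Hbb-y alone. Hba-x had 8.78 ± 0.416 kb and Hbb-y 4.94 ± 0.573 kb without a promoter peak of their own. The widest replicated peaks in the window of Hbb-y began 5344 and 7935 bp from its TSS, on the side of the locus control region. The value of this list thus need not belong to Hbb-y. The peaks in the window of Hba-x lay mainly at the Nprl3 promoter and at Hba-a1, so its covered length need not belong to Hba-x. Covered length at any other gene, such as Apom, can likewise include peaks of its neighbours, which were not told apart.

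Housekeeping genes had 4.85 ± 0.609 kb, with Polr2a at 9.66 ± 1.58 kb, Eef2 at 9.43 ± 1.41 kb, Chmp2a at 8.71 ± 0.583 kb and Tubb5 at 8.63 ± 0.850 kb. Ribosomal protein genes had 4.61 ± 0.631 kb, with Rpl7a at 11.5 ± 1.80 kb, Rpl13a at 11.2 ± 1.18 kb and Rpl23a at 11.2 ± 0.566 kb. Cell cycle genes had 4.48 ± 0.478 kb, with Rrm2 at 11.2 ± 1.11 kb, Aurkb at 9.93 ± 0.684 kb, Mki67 at 9.10 ± 0.955 kb and Pcna at 8.83 ± 0.255 kb. The H3K4 methylation machinery had 4.72 ± 0.238 kb, with the methyltransferase genes Setd1b at 15.4 ± 0.348 kb, Setd1a at 7.90 ± 0.664 kb and Kmt2d at 7.12 ± 0.266 kb. The lists below random were neurons with 0.579 ± 0.193 kb, developmental transcription factors with 0.743 ± 0.412 kb and Hox genes with 0.968 ± 0.427 kb. Tubb3 had 1.87 ± 0.595 kb, Pax6 1.86 ± 0.593 kb and Hoxa3 4.10 ± 1.28 kb, whereas Hoxa10, Hoxa11, Hoxb1, Dlx5 and Gad1 had no covered base.

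The other 12 lists were not apart from random in both replicates. Their medians were 0 kb for mature hepatocyte, myeloid, muscle, epidermal, pancreatic and intestinal, and olfactory genes. They were 0.863 ± 0.651 kb for megakaryocytes, with Gp1ba at 4.94 ± 0.725 kb, 0.217 ± 0.307 kb for lymphoid, 0.643 ± 0.660 kb for endothelial, 0.789 ± 0.567 kb for stellate and mesenchymal, with Reln at 7.64 ± 1.01 kb, 1.04 ± 0.131 kb for cholangiocyte, with Sox4 at 7.29 ± 0.671 kb, and 0.184 ± 0.260 kb for lung and kidney genes. In the last list Ager had 10.4 ± 1.14 kb without a promoter peak. The erythroid, heme, stem and progenitor, housekeeping and ribosomal protein calls held with each matching and window tried, whereas the other 7 ended in at least 1 of them. With random lists matched on promoter signal Hox genes lay above random (percentiles 99.9 and 99.9), and with lists matched on the number of neighbouring genes embryonic globins lay at percentiles 88.2 and 89.0, hepatoblast genes at 99.7 and 75.3 and neurons at 12.2 and 14.9.

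**Figure D3:**
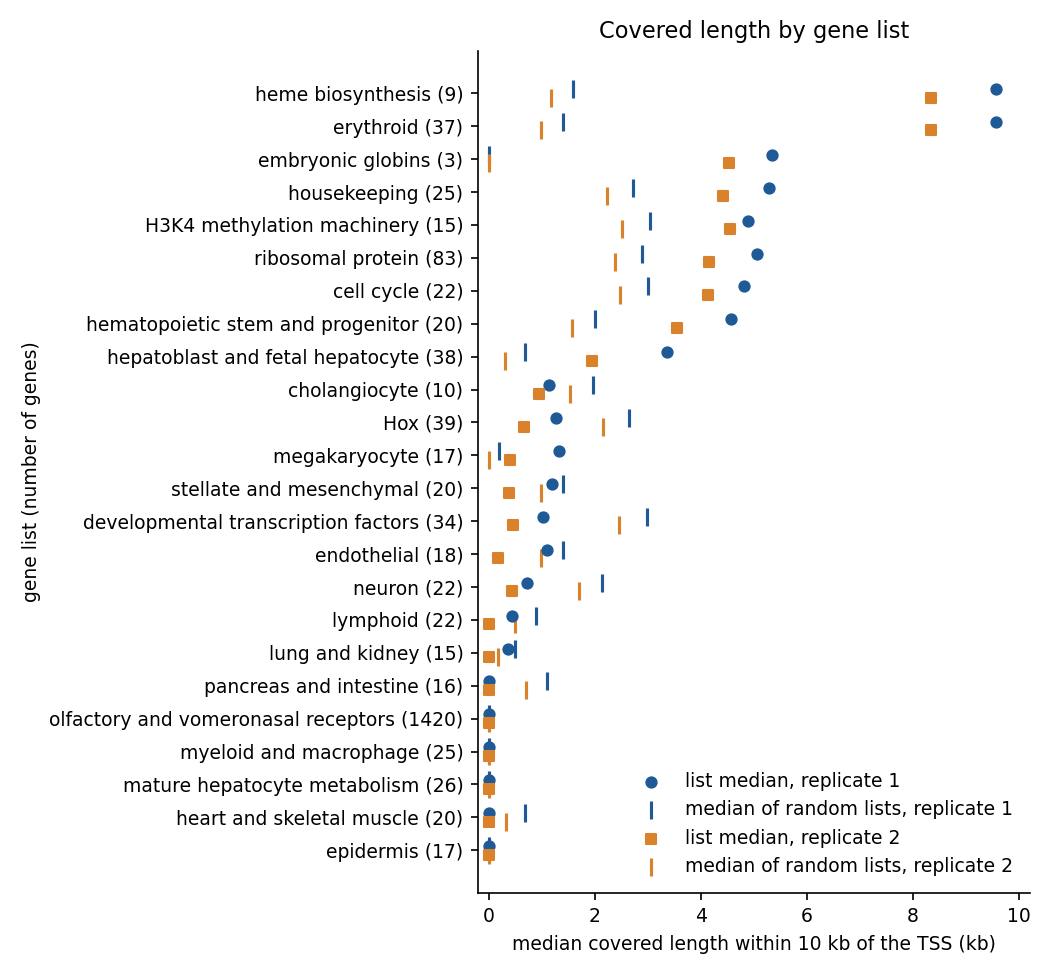
Median length covered by peaks within 10 kb of the TSS, in kb (x axis), for each gene list in replicate 1 (circles) and replicate 2 (squares), beside the median of random lists matched on promoter CpG content (vertical ticks). Erythroid genes had 9.57 and 8.34 kb against 1.39 and 0.982 kb for random lists.

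Several of the widest H3K4me2 domains lay at red cell genes. Replicated peaks merged over gaps of at most 1 kb formed 28662 domains, and 175 of them were wider than 10 kb. The widest, 35.7 kb on chromosome 8 at 23026632 to 23062355, lay inside Ank1, the gene of the red cell membrane protein ankyrin-1. Peaks of replicate 1 covered 98.3% of it and peaks of replicate 2 covered 90.0%. The next, 35.0 kb on the same chromosome, lay at Zfpm1, which encodes the GATA1 partner FOG-1, and at the overlapping model Gm20388. Then came domains at Ranbp10 with Tsnaxip1 (27.3 kb), Hemgn with Trmo (25.4 kb), Trak2 with Stradb (25.3 kb), and Nfe2 with Hnrnpa1 and Cbx5, on chromosome 15 at 103236662 to 103260648. The list of 10 ended with Rbm38 (21.4 kb), Tmcc2 (21.2 kb), Epb41 (21.1 kb) and Picalm (21.1 kb). Hemgn and Nfe2 are erythroid genes, the latter coding for a globin regulator, and Picalm acts in transferrin receptor uptake.

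Of the erythroid genes 17 of 37, or 45.9%, overlapped a domain wider than 10 kb (adjusted p = 1.66e-22 by Fisher's exact test), as did 4 of 9 heme biosynthesis genes (adjusted p = 1.59e-05), against 250 of 21938 protein-coding genes, or 1.14%. None of the 38 hepatoblast genes did, and no other list had more than 1 such gene. This count was chosen after the domains had been seen. The order of the widest domains depended on the merging. With peaks as deposited the widest was 18.4 kb at Rbm38, and with gaps of up to 3 kb it was 50.6 kb at Zfpm1.

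At single loci the globin clusters stood out against the albumin cluster. Each locus was taken with 50 kb either side. The α-globin locus, on chromosome 11, held 24 replicated peaks that began at Mpg, ran through the introns of Nprl3, where the known α-globin enhancers lie, and reached Hba-a1 and Hba-a2. Peaks covered 34.7% of it in replicate 1 and 29.2% in replicate 2. The β-globin locus on chromosome 7 held 29 replicated peaks and 19.1 and 14.5% coverage. The strongest, with signal 26.7, began 349 bp from the TSS of Hbb-bt, and further peaks lay beyond Hbb-y towards Olfr66, where the locus control region is known to lie. Hbb-bh1 had a promoter peak in replicate 1 alone. The cluster of Alb and Afp, 2 of the major plasma protein genes of fetal liver, held 15 peaks in replicate 1 and 2 in replicate 2, covering 3.46% and 0.358%, and none of its 6 replicated peaks had a signal above 4.79. Of these 3 lay in Alb, 1 in Afp and 2, the strongest among them, in the neighbouring gene Afm, chosen after its values were seen. The window around Hnf4a, a master regulator of hepatocytes, held 9 replicated peaks and had 6.94 and 4.61% coverage, but the strongest were promoter peaks of its neighbours Ttpal (signal 45.6) and Fitm2 (34.1), genes chosen after their values were seen. Peaks inside Hnf4a had signals of at most 7.24, and its promoter had a peak in replicate 1 and not in replicate 2. A replicate 2 peak with signal 4.29 did overlap the replicated peak that began 42 bp from the TSS of Hnf4a, but it lay just outside the 1 kb window.

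The windows around Tal1, Gata1 and the apolipoprotein genes likewise took in peaks at neighbouring genes. That of Tal1 had 11 replicated peaks and 21.3 and 17.2% coverage, that of Gata1 had 6 and 10.8 and 9.24%, and that of Kit had 6 and 5.41 and 4.49%. The locus of Apoa1, Apoc3, Apoa4 and Apoa5, apolipoprotein genes, had 5 replicated peaks and 6.14 and 4.70% coverage, none within 1 kb of a TSS of these 4 genes. The Hoxa locus, from Hoxa1 to Hoxa13 with 50 kb either side, had 23 replicated peaks, but coverage differed between the replicates, 9.05% against 3.50%. The Hoxd locus, from Hoxd1 to Hoxd13 with the same margin, had 8 and 2.52 and 1.23%. Coverage was lower in replicate 2 at each of the 10 loci, and so was coverage of the genome.

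**Figure D4:**
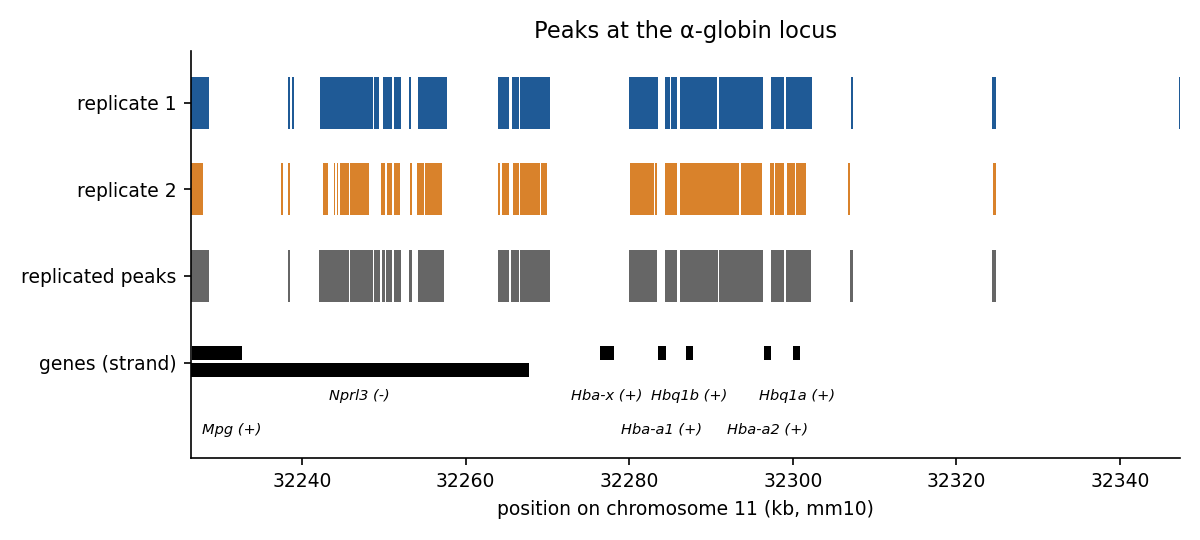
Map of the α-globin locus on chromosome 11 (x axis, kb, mm10) with the peaks of replicate 1, of replicate 2 and of the replicated list as bars and protein-coding genes with their strand beneath. Peaks covered 34.7% of the locus in replicate 1 and 29.2% in replicate 2.

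Promoter peaks were wider than distal peaks over each list as a whole, and more often shared. In replicate 1 promoter peaks, with a centre within 1 kb of a TSS, had a median width of 1626 bp and 87.3% of them (interval 86.8 to 87.8%) were shared with replicate 2. Distal peaks had a median width of 504 bp and 57.7% (57.2 to 58.3%) were shared. In replicate 2 the median widths were 1223 and 439 bp, and 99.03% of promoter peaks and 94.8% of distal peaks were shared. Within each of the 5 signal classes of replicate 1 the gap was smaller, for instance 89.0% of promoter and 85.9% of distal peaks in the middle class. In replicate 2 it was larger in the lowest class (92.4% and 86.8%) and smaller in the others. In the strongest class the order of widths was the other way, with medians of 2963.5 bp for distal and 2487 bp for promoter peaks in replicate 1, and 2369.5 and 1866 bp in replicate 2. By location 37.4% of replicate 1 peaks and 44.8% of replicate 2 peaks were at promoters, against 4.52% and 4.53% for shifted peaks. Intergenic peaks made up 18.4% and 15.8% against 50.1% and 50.1%, introns 39.6% and 35.0% against 42.3% and 42.3%, and exons 4.53% and 4.40% against 3.11% and 3.11%. Each share differed from the shifts with a one-sided permutation p of 0.001, the smallest that 1000 shifts can give.

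Distal peaks were denser than their flanks in several motifs of blood factors and in the liver motifs HNF1, CEBP and FOXA, though CEBP was not called against its reversed string. In the 21902 distal replicated peaks the log2 ratio over 36172 flanks at 5 kb was 0.32 ± 0.02 (jackknife SE over 21 chromosomes) for GATA, bound by the erythroid factor GATA1. It was 1.36 ± 0.09 for ETS, 1.02 ± 0.15 for NFE2, 0.92 ± 0.02 for KLF, 0.30 ± 0.14 for HNF1, 0.29 ± 0.05 for PU.1, 0.09 ± 0.04 for AP1, 0.08 ± 0.03 for FOXA, 0.06 ± 0.04 for RUNX and -0.0012 ± 0.11 for MEF2. RUNX and MEF2 were thus not clearly denser in peaks, while their reversed strings were sparser there (-0.32 ± 0.05 and -0.46 ± 0.12). The ratio of GATA exceeded that of its reversed string by 0.69 ± 0.02, and it was higher on 21 of 21 chromosomes, against 10 for NFE2, 14 for KLF and 16 to 20 for the others called higher. A chromosome where the difference could not be computed counted as not higher. The same difference was 1.41 ± 0.11 for ETS, 0.99 ± 0.45 for NFE2, 0.84 ± 0.18 for HNF1, 0.46 ± 0.18 for MEF2, 0.39 ± 0.06 for RUNX, 0.38 ± 0.04 for FOXA, 0.18 ± 0.05 for AP1, 0.18 ± 0.05 for PU.1 and 0.14 ± 0.04 for KLF. HNF1 and FOXA are motifs of liver factors, RUNX, PU.1, KLF and NFE2 of blood factors. These 10 motifs were also higher than permuted motifs with the same number of CpGs, a control chosen after the data were seen, with 0.54 ± 0.02 for GATA and 0.66 ± 0.09 for ETS. NFE2 had 316 matches in peaks, and its difference was -0.32 in the 500 bp around the summit. It was no longer called in the peaks of replicate 2 (0.38), nor was KLF (0.07), and MEF2 was not called with flanks at 20 kb (0.37).

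The string CAGATGG, used here for NEUROD, was sparser with either control, with differences of -0.25 ± 0.05 and -0.26 ± 0.02, but not in the 500 bp around the summit (-0.03). Such a short string need not be particular to neuronal factors, and which factors bind it was not tested. The calls of the other motifs depended on the control. REST, OCT and NFY were at -0.91 ± 0.27, -0.42 ± 0.17 and -0.10 ± 0.04 against the reversed motif, and at 0.07 ± 0.11, 0.07 ± 0.06 and 0.07 ± 0.04 against permuted motifs. CEBP was at -0.22 ± 0.14 against the reversed and 0.53 ± 0.08 against permuted motifs, CTCF at 0.18 ± 1.02 and 0.98 ± 0.18, and HNF4A at 0.04 ± 0.07 and 0.13 ± 0.06. Over flanks alone CEBP was at 0.21 ± 0.08, CTCF at 1.28 ± 0.15 and HNF4A at 0.04 ± 0.04, and the reversed string of CEBP at 0.43 ± 0.14. REST, OCT and NFY were at 0.17 ± 0.12, -0.17 ± 0.06 and -0.14 ± 0.03 over flanks, and NEUROD at -0.24 ± 0.02. RFX had no match of its reversed motif in the flanks and was at 1.52 ± 0.46 against permuted motifs.

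**Figure D5:**
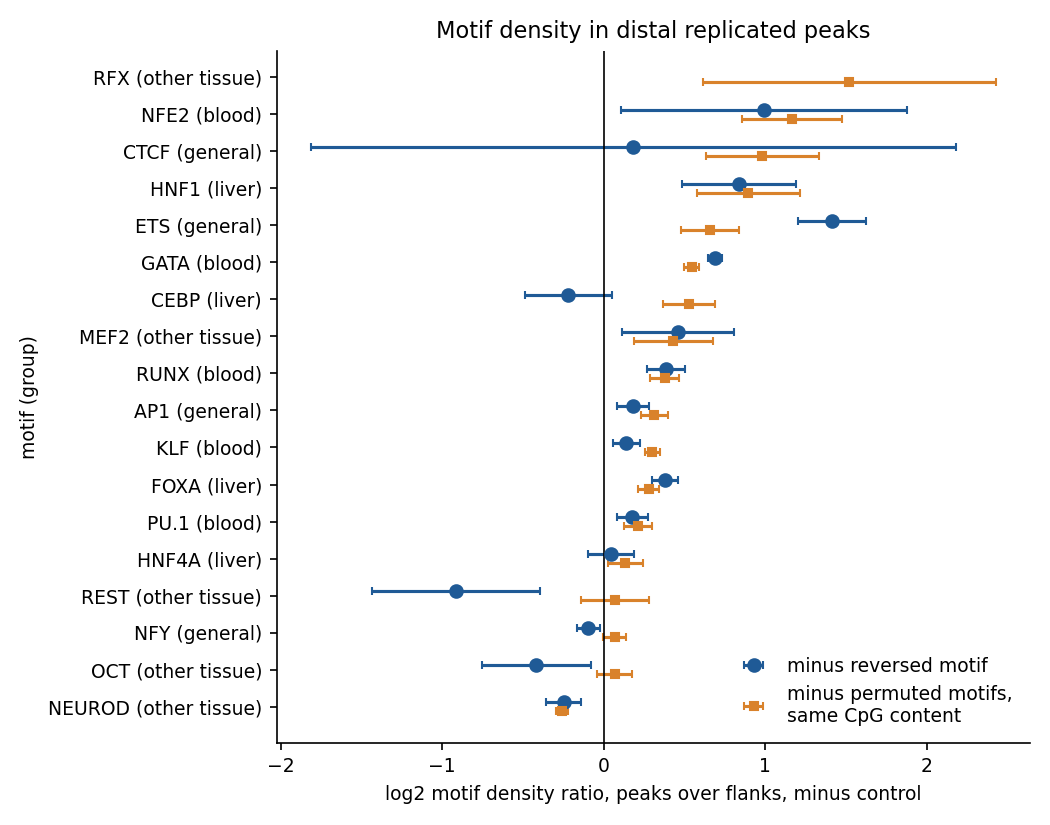
Log2 ratio of motif density in distal replicated peaks over flanks, minus that of a control (x axis), for 18 motifs with their group, with bars as 95% intervals from the jackknife over 21 chromosomes. Circles use the reversed motif and squares permuted motifs with the same CpG content; GATA stood at 0.69 and 0.54, and CEBP at -0.22 and 0.53.

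The X chromosome had fewer peaks per Mb than autosomes and also fewer genes, and the Y chromosome had almost no peaks. Peaks per Mb on X were 0.392 of the autosomal density in replicate 1 and 0.401 in replicate 2, and protein-coding genes numbered 5.80 per Mb on X, 2.08 on Y and 8.68 on autosomes. On X 49.3% and 45.0% of its 948 protein-coding genes had a promoter peak, against 67.1% and 64.4% on autosomes. The Y chromosome had 4 peaks in replicate 1 and 12 in replicate 2. Uty and Eif2s3y had a promoter peak in both replicates, Ddx3y and Kdm5d in replicate 2 alone. Xist, the RNA gene that silences an X chromosome in females, had 7.24 kb covered within 10 kb of its TSS in replicate 1 and 1.89 kb in replicate 2. Uty, Ddx3y, Eif2s3y and Xist were looked at after the peak counts of Y had been seen.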

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

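The counts of weak peaks, the chance test on Y genes and the comparison of Xist with autosomal genes were chosen only after the results were seen, as was the explanation by unmatched weak peaks, whose test was first written for fewer weak peaks and could not decide that. Peaks on contigs outside the 21 chromosomes, a part of the lists that no comparison used, numbered 12 in replicate 1, 9 in replicate 2, 14 in both together and 12 among the replicated peaks.

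Promoters of hepatocyte, endothelial and myeloid genes, such as Alb, Afp, Cd68 and Prtn3, had a peak in replicate 1 more often than in replicate 2. This direction was not particular to them. Over all protein-coding genes, 635 had a promoter peak in replicate 1 alone and 35 in replicate 2 alone. Whether replicate 2 had fewer weak peaks cannot be told, since the measures of weak peaks differ: with a -log10 q under 2 it had 4937 against 3772 in replicate 1, a difference of 1165, and with a signal under 4 it had 8705 against 11860. Of 277 replicate 1 peaks near 88 genes of a combined set for liver cells other than erythroid, 50.5% were shared. That set also holds genes outside the hepatocyte, endothelial and myeloid lists, so its result is not for these lists alone. Replicate 1 peaks of the same -log10 p gave 51.1%, which put the combined set at percentile 46.61 of random gene lists. Weak replicate 1 peaks being often unmatched in replicate 2, near the combined set as elsewhere, may account for the pattern there. Endothelial and myeloid genes were not tested apart from the combined set, so for each of them that explanation stays open. A smaller share of hepatocytes in replicate 2 would lower sharing near hepatocyte genes, but there 55.3% of 161 peaks, counted the same way, were shared against 52.2%, at percentile 90.57. No fall was seen, but the cutoff of that test, the 2.5th percentile of random lists, lay 5.4 points below peaks of the same -log10 p. That is a limit on the observed value, so a true fall near or under that size could be missed. A smaller share of hepatocytes thus stays open. So does an effect of the further files behind the lists (2 for replicate 1 and 1 for replicate 2), whose kind is not given and which was not tested.

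The Y chromosome had 4 peaks in replicate 1 and 12 in replicate 2 (2-sided exact binomial p = 0.0418 if peaks were independent, which neighbouring peaks are not). By gene, all 4 Y genes with peak bases had more in replicate 2, as did 3.34% of 15079 autosomal genes (chance 1.24e-06 if genes were independent), but this counts the same peaks again, so chance is not excluded. A larger share of male embryos in replicate 2 is a candidate explanation that stays open, and the test first written for it, single-copy Y genes with a promoter peak (2 in replicate 1 and 4 in replicate 2), restates the pattern too. Xist, on X, had a covered length in replicate 2 of 0.261 of that in replicate 1, where the median autosomal gene had 0.830 and 0.877% of autosomal genes had as low a ratio. The labels give both sexes for each pool and no proportions, so the share itself was not measured.

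Slc25a37 was an erythroid gene with no promoter peak in either replicate. Within 1 kb of its TSS 100% of the 32-mers had an exact copy elsewhere in the reference, so reads could be lost there if multiply mapped reads were left out, a step not given in the sources used here. Erythroid promoters with a peak had a median of 1.22% and at most 80.6%, at Hba-a2. Among CpG-rich promoters, 29.1% of 134 without a peak were mostly copied (interval 21.6 to 37.6%), against 0.746% of 134 with a peak (0.0189 to 4.09%). Car1, the other erythroid gene without a peak, had 0% copied, so copies leave it unexplained, and no biological explanation was tested.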

How the results depend on the processing

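Among the alternatives, classes by any part of the peak, the comprehensive annotation, random lists matched on promoter signal or on neighbouring genes, one gene per cluster, distal peaks with no part near a TSS and permuted motifs were chosen only after the data were seen. Sharing stayed above shifted lists in every setting run, from 59.6 to 81.6% of replicate 1 and 94.99 to 97.7% of replicate 2 peaks, and 61.8 to 65.8% of promoters had a peak. Without one replicate the share of promoters was 63.0 to 65.7%, the lists higher in promoter occupancy numbered 6 to 8 and those lower 8 to 10, the lists with longer covered length 9 to 9 and shorter 3 to 3, and the motifs higher 8 to 10 and lower 4 to 4. The signal correlation moved from 0.905 to 0.914 with at least 50% of the peak covered and to 0.903 at a -log10 q of at least 2, and the density on X relative to autosomes from 0.397 to 0.405 at that limit, where fewer peaks are counted. The widest domain changed from 35.7 kb to 18.4 kb without merging and to 50.6 kb with gaps of up to 3 kb, as merging itself sets the width. Lists with shorter covered length went from 3 to 5 with unmatched random lists, none of them the same lists, and to 0 with lists matched on promoter signal. There the medians, as means of the replicates, of neurons (0.579 kb), developmental transcription factors (0.743 kb) and Hox genes (0.968 kb) lay on the other side of random, those of developmental transcription factors in replicate 1 alone, and the first 2 within its central 95%. Developmental transcription factors, with promoter peaks at 66.2% as the mean of the replicates (73.5% in replicate 1 and 58.8% in replicate 2), lay above other genes in replicate 1 only, not called, and below random lists matched on promoter CpG. Motifs lower than the control went from 4 to 1 with permuted motifs, and NFY (0.0686), REST (0.0724), OCT (0.0670) and CEBP (0.53) changed sign, as did NFE2 in the 500 bp around the summit (-0.32); apart from the change in matching, merging or control itself, the cause was not tested. Of the values for single lists and motifs, 486 kept their call, 30 lost it, 19 gained one and 9 changed direction. RFX had no value against its reversed string. The depth is unknown, and what it limits was not tested.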

Other observations

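The 2 motif tests were written before their results were seen, and the counts by gene family, gene type and Hox cluster were chosen after the data were examined. Families of genes with a shared symbol stem and at least 20 members split sharply in promoter occupancy. Of 111 families 47 had promoter peaks more often than other genes in both replicates and 31 less often (Fisher's exact test, adjusted p under 0.05). The families were not matched on promoter CpG content, which occupancy followed. Nor was sequence copied between family members taken into account, so a missing peak there need not mean a missing mark. All 49 Mrpl and all 29 Mrps genes, both of mitochondrial ribosomal proteins, were occupied in both replicates. So were all 30 Mediator genes (Med), all 35 vacuolar sorting genes (Vps) and all 28 RNA polymerase genes (Polr). Zinc finger genes (Zfp) had peaks at 349 of 394 promoters in replicate 1 and 345 in replicate 2. No peak was found at the promoters of 42 β-defensins (Defb), 57 keratin-associated proteins (Krtap), 34 reproductive homeobox genes (Rhox), 26 prolactin-like hormones (Prl) or 22 major urinary proteins (Mup), the last a liver product of adult mice. Cytochrome P450 genes (Cyp) had peaks at 27 of 100 promoters in replicate 1 and 23 in replicate 2, and Serpina genes at 7 and 2 of 24.

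Noncoding genes varied as widely. Of 190 lncRNAs annotated at bidirectional promoters 90.5% had a peak within 1 kb of an annotated TSS in replicate 1 and 90.0% in replicate 2. The shares were 37.6% and 34.0% of 2959 antisense RNAs and 17.6% and 14.6% of 5854 lincRNAs. They were 17.1% and 15.1% of 2202 microRNA genes and 3.02% and 2.28% of 9940 processed pseudogenes. An annotated TSS need not be the start of the primary transcript, and its window can hold the promoter of another gene, which was not told apart. Among the Hox clusters, taken without a margin, peaks covered 16.4% of Hoxa in replicate 1 and 6.53% in replicate 2, 6.17 and 2.00% of Hoxb, 2.22 and 1.06% of Hoxc and 4.19 and 2.42% of Hoxd.

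One hypothesis was that GATA motifs are denser in distal peaks near erythroid genes than near hepatocyte genes. The densities were 0.758 per kb in 241 peaks near 34 erythroid genes and 0.584 per kb in 127 peaks near 33 hepatocyte genes (2-sided permutation p = 0.0969). Motifs of the liver factors HNF4A, HNF1, FOXA and CEBP, taken as a group, had 0.236 per kb near erythroid and 0.288 per kb near hepatocyte genes (p = 0.295 by the same permutation test). Neither difference passed 0.05, and with this number of genes it stays open whether these densities differ.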
